A study of Homo sapiens with 6 samples.

How the data were processed

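H3K9me3, the trimethylation of lysine 9 on histone H3 that marks repressed heterochromatin, was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) in BJ cells, an established line of human skin fibroblasts. The cells carried CRISPR interference, in which a guide RNA brings a repressor to a gene, with a control guide or with 1 of 2 guides against PURPL, a long non-coding RNA gene induced by p53. Each of the 3 cell lines gave 1 H3K9me3 library and 1 input library, 6 samples in all. Per the labels' protocols, cells were fixed with 1% formaldehyde for 10 min.

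The deposited file of each H3K9me3 sample is a list of peaks with a position and a score per peak, 1 list per cell line, so peaks were called per sample and not on pooled samples. Per the submitters' processing notes, the tools were Bowtie2 2.4.2, GATK, MACS2 2.2.9.1 and deepTools 3.5.1, with the builds hg38 and GRCh38.p13. Each list is named as H3K9me3 against the input library of the same cell line. The peak-calling settings and the read numbers are not given in the sources used here. The deposited score is the authors' own value for each peak, a whole number of at least 10 in every list, on a scale the sources used here do not name. It served mainly to rank or filter peaks within a list. Across lists it served for filters that set 1 score limit for all 3 lists, and to rank regions of both guides by the lower of their scores. The peak names inside the lists carry other guide names than the labels, so each list was assigned by its sample's labels. The sequencing depth is unknown, and no value here is corrected for it.

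Peaks on chromosomes 1 to 22 and X were analysed. The remaining sequences, any peaks on chromosome Y included, held 4.34% of the control peaks, 4.27% of the guide 1 peaks and 3.85% of the guide 2 peaks. Gene positions came from a RefSeq gene table for GRCh38.p14, whose chromosomes have the same coordinates as GRCh38.p13. The table gives the start and end of each gene without strand or exons, so transcription start sites and the exonic or intronic place of a peak were not used here. A peak was shared when it overlapped a peak of the other list by at least 1 bp. Chance overlap was measured by placing the peaks of 1 list at random on their chromosomes 200 times, and at the local peak density by moving them 20000 bp to either side. A protein-coding gene was called marked when a peak overlapped its body, and its covered length is the number of its bases under peaks. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, with a fixed random seed.

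With 1 library per cell line, no difference between cell lines has a replicate check, and no p-value or SD is given. Shares of peaks carry 95% Wilson intervals, which cover counting error only. The 18 gene lists, the comparisons and the alternatives were fixed before the data were examined, apart from those said to be chosen after seeing the data. For each list, the median change of the share of gene length under peaks was ranked among 10000 random lists of the same size, matched on gene length and control coverage. The share of a list's control coverage left in each guide was ranked among the same random lists, a measure added after the data were seen. For this rank coverage was summed over genes, so bases shared by overlapping genes count once per gene. These percentiles describe these libraries and are not tests of the knockdown.

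Genes were named by a rule fixed before the data were examined. It takes PURPL with the nearest protein-coding gene on each side, the 10 genes with the longest control coverage and none in either guide, and the 10 with the largest reduction in both guides. It also takes the 10 with peaks in both guides and none in the control, the 10 with the largest increase in both guides among control-marked genes, and the 5 with the longest coverage common to all 3 lists. Up to 3 members per gene list with the longest control coverage were added, with the 3 highest-scoring peaks of the control alone, of both guides alone, ranked by the lower of their scores, and of all 3 lists, ranked by the control score. 1 gene of the senescence list is not reported here and was left out of that list. Names outside the rule are said to be chosen after their values were seen.

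Gene-free stretches are the 30 intervals of at least 1 Mb between neighbouring annotated genes of any kind, 177 Mb in total. This division was chosen after the data were seen, and it replaced an earlier one, the longest such interval of each chromosome, whose values are given with the alternatives. The overlap and list methods were tested on simulated data. Simulated guide lists were random subsets of the 22627 control peaks, scored under the 1 bp rule and a reciprocal one. Over 6 such runs, 100% of the kept and 0% of the removed peaks were called shared. These lists had no moved edges and no new peaks, so the runs check the calculation and not the overlap rule in these data. A simulated list of 60 genes with its coverage removed fell at percentile 0 of the share left, and an unchanged one at percentile 19.7. Alternatives covered other sequences, peak width, score limits, merging of neighbouring peaks, stricter overlap, lists of equal length, gene flanks, all annotated genes and matching on length alone.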

Results

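H3K9me3 peaks were compared between BJ fibroblasts carrying a control guide and BJ fibroblasts carrying PURPL guide 1 or PURPL guide 2, to ask how the mark differs when PURPL is targeted. Each cell line had 1 H3K9me3 library and 1 input library. On chromosomes 1 to 22 and X of GRCh38, the control list held 22627 peaks, the guide 1 list 14087 and the guide 2 list 11721. The depth of the libraries is unknown, so the number of peaks that each could yield is unknown too. No difference below has a replicate check.

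PURPL, the targeted gene (gene ID 643401, chromosome 5, 27472292 to 27496401), had 0 peaks in its body in all 3 lists, and 0 with 5000 bp added on each side. The nearest control peak lay 113.8 kb away, at 27358045 to 27358455. The nearest guide 2 peak lay 45.5 kb away, at 27426468 to 27426783, with a score above 91.4% of the peaks in its list. Guide 1 had 0 peaks within 500 kb of the gene. The flanking protein-coding genes, the cadherin gene CDH9 at 434 kb and LOC124901178 at 1429 kb, had 0 covered bases in all 3 lists. The PURPL transcript was not analysed here, so these lists do not show how far each guide lowered it.

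H3K9me3 peaks were fewer and narrower with both PURPL guides than with the control guide. Guide 1 had 62.3% of the control number of peaks and guide 2 had 51.8%. The length under peaks was 32.3 Mb in the control, 17.0 Mb with guide 1 and 13.1 Mb with guide 2, so the guides had 52.4% and 40.3% of the control length. Median peak width was 858 bp in the control, 810 bp with guide 1 and 785 bp with guide 2. The widest peaks differed most in number, with 217, 31 and 8 of at least 10000 bp. A domain called as several shorter peaks also drops out of this count. With peaks within 5000 bp merged, the guides had 61.9% and 52.2% of the control length.

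**Figure D1:**
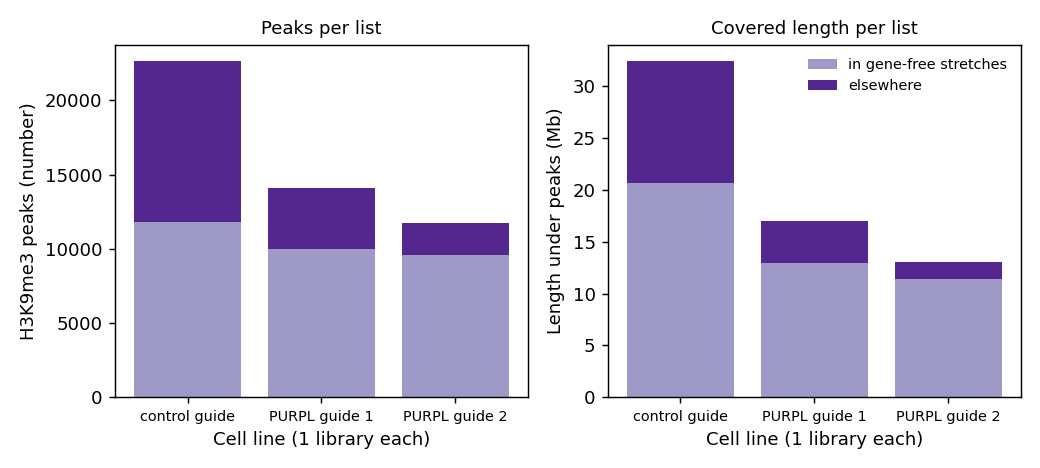
Stacked bars give the number of H3K9me3 peaks (left) and the length under peaks in Mb (right) in the control, PURPL guide 1 and PURPL guide 2 lists, 1 library each, divided into gene-free stretches of at least 1 Mb and the remaining genome. The control list covers 32.3 Mb and the guide lists 17.0 and 13.1 Mb, and the part outside the stretches is 11.7, 3.98 and 1.65 Mb.

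The remaining coverage lay largely in gene-free stretches, which on most chromosomes span the centromere and its satellite repeats. Inside these stretches the guides had 62.9% and 55.3% of the control length. Outside them they had 33.9% and 14.1%. The stretches held 52.3% of the control peaks, 71.0% of the guide 1 peaks and 81.9% of the guide 2 peaks. The division into stretches was chosen after the data were seen.

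In each of the 23 stretches with at least 100 control peaks, 1 per chromosome, the covered length was shorter in both guides than in the control. The share left ranged from 17.9% to 80.9% with guide 1 (median 62.8%) and from 21.9% to 70.6% with guide 2 (median 54.1%). Chromosome X had the lowest share with each guide, 17.9% and 21.9%, where 379 control peaks stood against 84 and 110. Its control peaks also had the smallest mean width of the 23 stretches, 776 bp. Chromosome 18 followed with guide 1 (37.0%) and chromosome 16 with guide 2 (38.6%). Chromosome 8 kept 80.9% and 68.9%, and chromosome 6 kept 80.2% and 70.6%. Of the 23, chromosomes 13, 14, 21 and 22 kept 58.5% to 62.8% with guide 1 and 50.6% to 54.1% with guide 2. Their control lengths were also close, from 656 to 705 kb. Reads of satellite repeats may fit more than 1 chromosome, which was not tested here. The 23 stretches may therefore not be separate observations. In 6 of the 23 stretches both guides had more peaks than the control over a shorter length, as on chromosome 8, where 322, 401 and 473 peaks had mean widths of 4366, 2837 and 2047 bp.

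**Figure D2:**
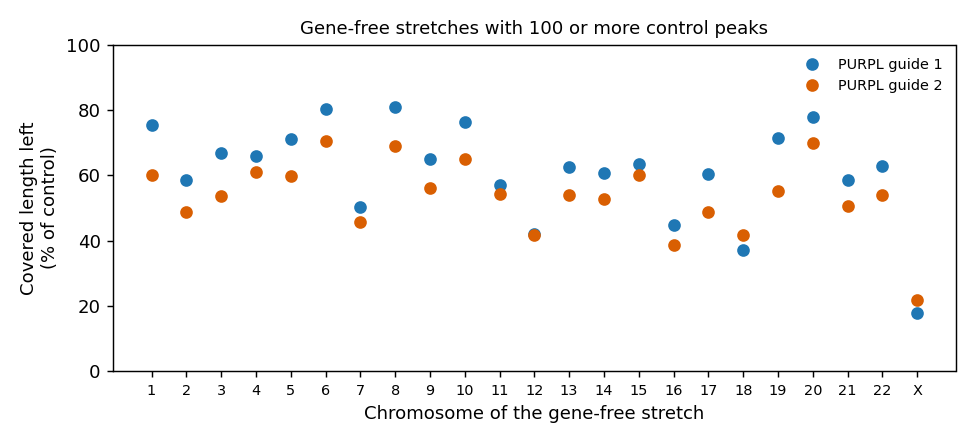
Each point is the length under H3K9me3 peaks in a gene-free stretch, in percent of the control length in the same stretch, for PURPL guide 1 and PURPL guide 2, with the 23 stretches of at least 100 control peaks ordered by chromosome. All points lie below 100%, from 17.9% to 80.9% with guide 1 and from 21.9% to 70.6% with guide 2. Chromosome X is lowest with each. Reads of repeats may fit more than 1 chromosome, so the stretches may not be separate observations.

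Among control peaks, 42.8% overlapped a guide 1 peak (95% Wilson interval 42.1 to 43.4) and 36.2% a guide 2 peak (35.6 to 36.8). Random placement of the guide peaks gave 1.69% and 1.32%, and moving them by 20000 bp gave 26.2% and 23.8%. Outside the stretches, 18.2% of the control peaks overlapped guide 1 and 9.14% overlapped guide 2, against 4.46% and 2.59% after the move. Overlap with guide 1 was found for 11.0% of the control peaks in the lowest decile of score and 86.0% in the highest. For guide 2 the shares were 6.32% and 80.9%. Beyond local chance the shares were 5.40% and 73.9% for guide 1, and 1.74% and 67.1% for guide 2. Score and place go together, as 1878 of the 2263 peaks in the lowest decile lay outside the stretches. In the highest decile 49 of 2263 did. The share of all control peaks depends on the overlap required and fell to 26.7% and 20.4% when at least 50% of the control peak had to be covered.

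**Figure D3:**
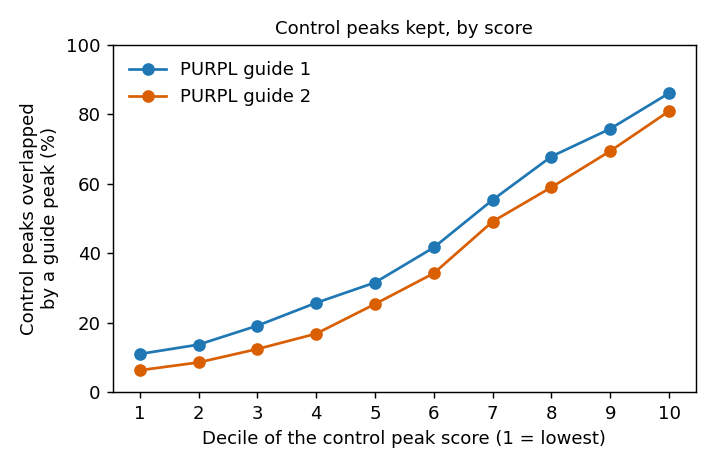
Points give the share of control peaks, in percent, that a guide peak overlapped by at least 1 bp, per decile of the authors' score in the control list, for PURPL guide 1 and guide 2. The share goes from 11.0% to 86.0% with guide 1 and from 6.32% to 80.9% with guide 2. Local chance overlap is not subtracted.

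Most guide peaks lay on control peaks, 79.2% with guide 1 and 82.9% with guide 2, against 48.3% and 53.9% at the local peak density (moved by 20000 bp). Of the guide 1 peaks, 2925 overlapped no control peak (20.8%, Wilson interval 20.1 to 21.4), and of the guide 2 peaks 1999 (17.1%, 16.4 to 17.7). Outside the stretches these shares without a control peak were 43.4% and 41.0%, and in the upper score quartile of each guide 7.64% and 6.88%. The guide lists also differed from each other, as 55.0% of the guide 1 peaks overlapped a guide 2 peak and 68.6% of the guide 2 peaks overlapped a guide 1 peak, against 33.0% and 40.9% after the move.

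In the control, 11325 peaks (50.1%, Wilson interval 49.4 to 50.7) overlapped no peak of either guide, and 14.7% of those in the upper score quartile. Independent lists would share 8261 such peaks, and 9738 when independence was taken within deciles of score. In the gene-free stretches alone 2856 such peaks stood against 1609 (1977 within deciles), a ratio of 1.78. Elsewhere, 8469 stood against 8026 (8129 within deciles), a ratio of 1.06. The excess over all peaks is larger than these parts together, because the share lost differs between them. Both comparisons use the same control library, so part of the excess may come from it. The 3 highest-scoring peaks of this class lay in gene-free stretches, at 26566922 to 26567149 on chromosome 17, 48498076 to 48498401 on chromosome 5 and 26443733 to 26444002 on chromosome 19. Peaks of both guides overlapped each other without a control peak in 369 regions, 284 of them in gene-free stretches. Most lay next to control peaks, and 53 remained when a control peak within 5000 bp counted as present. Ranked by the lower of the guide scores, the first 3 were at 143235680 to 143235909 on chromosome 1, 17484059 to 17484296 on chromosome 14 and 17361779 to 17362019 on chromosome 13, none in an annotated gene. The 3 highest-scoring control peaks with a peak in all 3 lists lay on chromosome 1, at 125178838 to 125183874, 143230138 to 143233625 and 143200196 to 143203574.

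Fewer protein-coding genes were marked with the PURPL guides. Of 19974 genes, 2610 carried a peak in the control, 1308 with guide 1 and 745 with guide 2. Coverage was shorter in both guides for 2417 control-marked genes (92.6%) and longer in both for 15. It was longer with guide 1 and shorter with guide 2 for 132, and the reverse for 37. Every peak was absent in both guides for 1370 of the 2610 control-marked genes. Among all annotated genes this held for 2335 of 4115, and at gene ends for 241 of 544. Independent lists would share 1181 such coding genes, a number that ignores gene length and the shared control. Gene bodies had 36.7% of the control coverage with guide 1 and 14.3% with guide 2.

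Genes covered over the longest length in the control and at 0 in both guides came from several functions. AFG2A, an AAA-type ATPase gene, had 7707 control bases under peaks, the transcription factor gene RFX7 7325, the cyclin-dependent kinase gene CDK14 6934 and the phospholipase C gene PLCB1 6636. The zinc finger gene ZNF454 followed with 6059, then CNTLN with 5645, DNAJC1 with 5443, the ceramide transfer protein gene CERT1 with 5416, FBXL2 with 4946 and the kinase gene MAP2K5 with 4539. With peaks limited to scores at or above the pooled median, 6 of these 10 genes had 0 covered bases in all 3 lists, and RFX7, CNTLN, DNAJC1 and CERT1 stayed marked in the control alone.

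Zinc finger genes, many of which encode DNA-binding repressors and carry H3K9me3 over their bodies, held the longest coverage of any list. Of 559 members, 335 were marked in the control, 287 with guide 1 and 221 with guide 2. Their coverage was 2904 kb, 1412 kb and 553 kb, so 48.6% and 19.03% of the control length was left. At or above the pooled median score these shares were 37.3% and 8.57%. Coverage was shorter in both guides for 316 members and longer in both for 0. The median change was -1.61 percentage points of gene length with guide 1, at percentile 20.8 of the matched random lists (0 when matched on length alone), and -3.81 with guide 2, at percentile 0. The share of coverage left was above that of the random lists, whose middle 95% ran from 36.1% to 41.5% for guide 1 and from 11.7% to 14.9% for guide 2. When matched on length alone it ran from 16.2% to 43.2% and from 3.49% to 19.35%, so the share with guide 2 lay inside. With guide 2 the median change and the share left thus stand on opposite sides of the random lists matched on length and coverage. With guide 1 the median change lay within them. Control coverage was matched in 5 classes only, and this list held 2904 kb of the 6.09 Mb of control coverage in gene bodies. The match may therefore set its members beside genes with less coverage.

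Individual zinc finger genes differed widely. ZNF91, a repressor of SVA retrotransposons, had 42.7 kb under peaks in the control, 25.6 kb with guide 1 and 7.73 kb with guide 2. The largest reductions in both guides were at ZNF578 (37603, 10705 and 2395 bp), ZNF717 (40645, 13858 and 5462 bp), ZNF569 (36771, 10620 and 2026 bp) and ZNF718 (37291, 13288 and 2772 bp). ZNF420, ZNF540, ZNF559-ZNF177, ZNF44, ZNF626 and the protocadherin gene PCDHGA1 completed this group of 10. The longest coverage common to all 3 lists was at ZNF544, with 31465 bp in the control, 28187 bp with guide 1 and 14602 bp with guide 2. ZNF69 (37884, 22016 and 13223 bp), ZNF274 (28801, 23870 and 12781 bp), ZNF605 (32742, 20205 and 12564 bp) and ZNF721 (31763, 20583 and 12215 bp) followed. ZNF274 itself encodes a protein that recruits H3K9 methylation to zinc finger genes.

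A cluster on chromosome 19 from 36900001 to 37700000, chosen after its values were seen, holds 13 zinc finger genes among 14 coding genes. It had 281 kb under peaks in the control, 121 kb with guide 1 and 40.1 kb with guide 2. The number of peaks was close in the control and guide 1, 96 and 90, against 42 with guide 2. The longest peak measured 18.5, 5.67 and 3.34 kb.

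**Figure D4:**
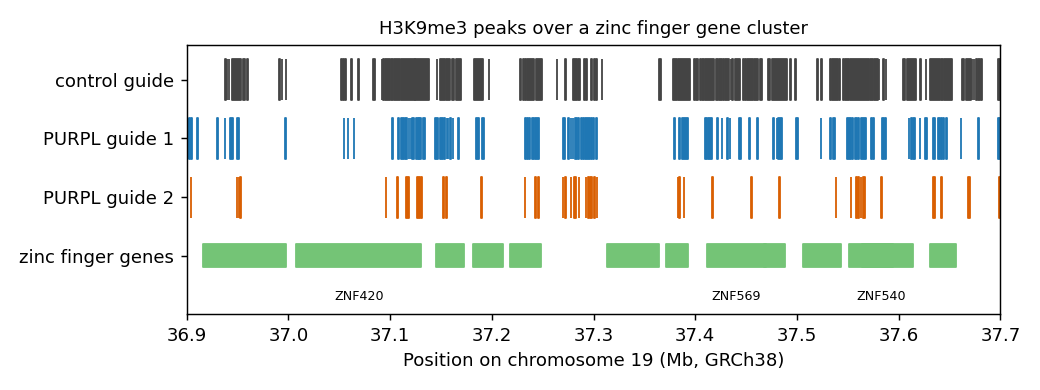
Map of chromosome 19 from 36.9 to 37.7 Mb (GRCh38), with the H3K9me3 peaks of the control, PURPL guide 1 and PURPL guide 2 lists as blocks to scale, and the bodies of the zinc finger genes below. Covered length is 281, 121 and 40.1 kb in the 3 lists, and the longest block measures 18.5, 5.67 and 3.34 kb.

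Clustered protocadherins, neural adhesion genes in 1 cluster on chromosome 5 with overlapping bodies, had 24 of 53 members marked in the control, 20 with guide 1 and 18 with guide 2. Their joint coverage was 24.4, 4.97 and 1.28 kb, which left 20.4% and 5.23% (0% with guide 2 at or above the pooled median score). Summed over genes, so that shared bases count once per gene, 18.4% and 4.66% was left, at percentiles 6.29 and 2.83 of the random lists. When matched on length alone the percentiles were 27.1 and 23.2. The random lists draw genes singly and lack such overlap, so these percentiles are not a like comparison. PCDHGA1, PCDHGA2 and PCDHGA3 share most of their length and had 22551, 22400 and 21475 bp in the control, and each had 4666 bp with guide 1 and 921 bp with guide 2.

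Neuronal genes, many of them very long, had 12 of 30 members marked in the control (40%, against 13.1% of all coding genes), 5 with guide 1 and 4 with guide 2, with 20.1, 2.53 and 2.10 kb. The share left, 12.6% and 10.4%, lay at percentiles 12.0 and 66.1 of the random lists. Guide 2 had no coverage of these genes at or above the pooled median score. Among them the potassium channel partner KCNIP4 had 5155, 0 and 636 bp, the synaptic vesicle gene SYT1 4400, 862 and 222 bp, and the synaptic adhesion gene NLGN1 3452, 0 and 0 bp. The other lists of genes foreign to fibroblasts had few marked members. Of 392 olfactory receptor genes, 6 were marked in the control and 0 in either guide, among them OR9Q1 with 846 bp and OR1F1 and OR1L4 with 567 bp each. This holds for gene bodies, as 25.5% and 7.57% of the control coverage was left at the ends of these genes. Blood genes had 2 marked members in the control (CD8A, 787 bp, and KLRD1, 282 bp), endothelial genes 1 (ERG, 391 bp) and melanocyte genes 1 (MITF, 1384 bp), with 0 in either guide. Keratin and epidermal, beta-defensin, HOX and hepatocyte lists had 0 marked members in all 3 cell lines.

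Imprinted genes had 3 marked members in the control, 2 with guide 1 and 1 with guide 2. The share of coverage left, 41.7% and 7.90%, lay at percentiles 85.55 and 66.4 of the random lists. KCNQ1, a potassium channel gene in an imprinted domain, had 17381 bp under peaks in the control, 7541 bp with guide 1 and 1498 bp with guide 2. PLAGL1 (947 bp) and UBE3A (627 bp) were marked in the control alone, and BLCAP, named after its values were seen, with guide 1 alone (359 bp). Germline genes had 1, 1 and 2 marked members, and 95.3% and 43.9% of the control coverage. The RNA helicase gene DDX4 had 1074, 0 and 228 bp. The meiotic gene SYCP1 had 1023 bp with guide 1 alone and TEX11 243 bp with guide 2 alone, both named after their values were seen. Ribosomal protein genes had 1 marked member in the control, RPS16 with 370 bp, and 0 in the guides.

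Genes of H3K9 methylation itself had 6 of 24 members marked in the control, 5 with guide 1 and 1 with guide 2. All 6 were shorter in both guides, as were 92.6% of all control-marked genes. The share left, 27.5% and 3.94%, lay at percentiles 69.15 and 39.4 of the random lists. ATF7IP, a partner of the methyltransferase SETDB1, had 7395, 1351 and 0 bp. The demethylase gene KDM4B had 2521, 926 and 500 bp, and SETDB1 863, 232 and 0 bp. At or above the pooled median score KDM4B was 178 bp longer with guide 1 than in the control, and at gene ends the list had 0% of the control coverage with guide 1. Fibroblast matrix genes had 7 of 34 members marked in the control, 2 with guide 1 and 1 with guide 2. The share left, 27.0% and 18.5%, lay at percentiles 30.0 and 62.0 of the random lists. At or above the pooled median score neither guide covered any of these genes. The proteoglycan gene DCN had 3288 bp in the control and 0 in both guides.

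Lists tied to p53 and senescence had few marked genes. Of 33 p53 targets, 1 was marked in the control, 3 with guide 1 and 0 with guide 2, with 1498, 2479 and 0 bp. The longer coverage with guide 1 was lost in other settings, at 0% of the control at or above the pooled median score and 71.2% at gene ends. MDM2, the ubiquitin ligase that degrades p53, had 1498, 809 and 0 bp. The guide 1 list also marked the DNA repair gene XPC (1106 bp) and the death receptor gene TNFRSF10B (564 bp), named after their values were seen. Of 38 senescence and secretory genes analysed, 0 were marked in the control, 1 with guide 1 and 0 with guide 2. The growth factor gene EREG, named after its values were seen, had 738 bp with guide 1.

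Peaks in both guides and none in the control occurred at 24 genes (39 among all annotated genes, 9 at gene ends). Independent lists would share 1.90, or 4.93 within deciles of gene length, a number added after the data were seen, but neither number accounts for repeat content or the shared control library, so the excess is not a measure of a shared effect. Of these, 6 were copies of the deubiquitinase family USP17L in a tandem array on chromosome 4, and their near-identical sequences leave the copy of origin uncertain. USP17L25 had 1401 bp with guide 1 and 1593 bp with guide 2, and USP17L30, USP17L5, USP17L26 and USP17L19 were also among the 10 longest. With 5000 bp flanks, USP17L30 with guide 2 and USP17L19 with guide 1 were below the control (-2238 and -1273 bp). The others were SH3GL3 (676 and 553 bp), the histone methyltransferase gene KMT2C (542 and 512 bp), the phosphodiesterase gene PDE5A (1251 and 491 bp), the mitophagy gene BNIP3L (1275 bp with guide 2 and a shorter peak with guide 1) and the zinc finger transcription factor gene KLF6 (577 and 407 bp). Among control-marked genes, the longest increases in both guides were at USP17L20, RAG1 (396, 1525 and 1143 bp), MRPS9, SMOC2, GPAM, DUSP1, PTPRN2, CAMK1D, APPL2 and DUX4, a gene in a repeat array. At the phosphatase gene DUSP1 the increase held for the gene body alone, as its control peak lay mostly beyond the gene end. USP17L20 was below the control with guide 2 when 5000 bp flanks were added (-721 bp). At or above the pooled median score, 2 of the 10 genes with peaks in both guides alone (USP17L5 and USP17L19) and 4 of the 10 with the longest increases (USP17L20, SMOC2, CAMK1D and DUX4) showed the same pattern, while GPAM (-419 bp) and PTPRN2 (-70 bp) with guide 1 fell below the control.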

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

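Tests of explanations in this part were chosen after the result was seen. With 1 library per cell line, none of the differences between the guides was tested.

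Among the gene lists and the genes named by the fixed rule, covered length moved in opposite directions in the guides for 1 list and a pair of genes. For p53 targets it was 981 bp longer than the control with guide 1 and changed by -1498 bp with guide 2. THBS1, which encodes the matrix protein thrombospondin 1 (chromosome 15, 39581079 to 39599466), was 477 bp longer with guide 1 and changed by -1204 bp with guide 2. CCN1, a matrix gene of the serum response (chromosome 1, 85580761 to 85583950), changed by -617 bp with guide 1 and was 357 bp longer with guide 2. The list difference rests on at most 3 marked genes per cell line. With 5000 bp flanks both genes kept their opposite directions, THBS1 at 477 and -1204 bp and CCN1 at -423 and 96 bp. At or above the pooled median score none of these 3 kept them, as the p53 list had 0% of the control coverage with each guide, and THBS1 changed by -249 bp and CCN1 by -1182 bp with each. At gene ends the p53 list had 71.2% and 0%. At that score limit GPAM (-419 and 359 bp), PTPRN2 (-70 and 261 bp) and KDM4B (178 and -748 bp) took opposite directions instead, and with flanks USP17L30 (2445 and -2238 bp), USP17L20 (533 and -721 bp) and USP17L19 (-1273 and 466 bp) did.

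Among the unplaced and patch sequences that the comparisons left out, 7 of 210 were covered over a longer length in both guides than in the control, and 157 over a shorter one. Their summed coverage was 1153 kb in the control, 658 kb with guide 1 and 425 kb with guide 2. Chromosome Y is not part of these numbers.

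The reduced number of peaks in both guide lists may reflect lower sensitivity of the guide libraries, through depth or enrichment. Control peaks of the highest score decile were kept more often than those of the lowest by 75.0 percentage points with guide 1 and 74.5 with guide 2, as lower sensitivity predicts. Outside the stretches the differences were 59.5 points (95% interval from redrawn 1 Mb blocks 35.4 to 76.3) and 46.4 points (24.7 to 67.0), from 49 peaks in the highest decile. A real reduction of H3K9me3 that is similar everywhere would give the same order, so this test does not separate it from sensitivity. An effect of the PURPL guides stays open and was not tested, because each cell line gave 1 library.

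The larger loss outside the gene-free stretches was set against chance overlap and against uniformly lower sensitivity. The share of control peaks overlapped was higher inside than outside by 47.0 points with guide 1 and 51.8 points with guide 2. Counting only overlap beyond local chance, the difference was 21.2 points (17.5 to 25.03) and 24.5 points (20.9 to 28.6), which argues against chance overlap as the whole cause. Among control peaks of the same score decile and width class, the share kept beyond local chance differed between inside and outside by -1.48 points with guide 1 (-4.26 to 0.218) and 4.40 points with guide 2 (2.49 to 6.71). Lower sensitivity therefore stays a candidate explanation for the gap in overlap, since matching on score and width left little of it in percentage points. The match was weighted by the peaks outside the stretches, of which 14.4% and 6.73% were kept beyond local chance. Beside so low a share the 4.40 points with guide 2 are not small, and their interval lies above 0. The move of 20000 bp may also count overlap within 1 broad domain as chance. A knockdown effect that acts more on weak peaks stays open too. In covered length, the share left was higher inside than outside by 29.02 points with guide 1 and 41.26 points with guide 2. The gap in length was not matched on score or width, so the matched values do not show what accounts for it.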

How the results depend on the processing

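Peak number and covered length stayed below the control in both guides under every alternative run. The guides' percentages of the control peak number (guide 1, then guide 2) were 59.7% and 48.4% for peaks of at least 500 bp, 68.7% and 57.5% at or above the pooled median score, 66.2% and 54.3% at or above the pooled upper quartile, and 52.0% and 39.8% with peaks within 5000 bp merged. Covered length was 39.1% with guide 2 for peaks of at least 500 bp, 48.7% and 35.9% at the pooled median, 42.9% and 31.5% at the upper quartile, and 61.9% and 52.2% after that merging. All sequences and merging within 1000 bp stayed within counting error. Leaving out the gene-free stretches, chosen after seeing the data, gave 37.8% and 19.6% of the number and 33.9% and 14.1% of the length. With the earlier definition, the longest stretch of each chromosome, the length outside was 37.9% and 19.8%.

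Shared control peaks were 26.7% and 20.4% with 50% of the control peak covered, 19.8% and 15.2% with reciprocal overlap, 48.4% and 41.3% at the pooled median score, 78.1% and 71.4% for the upper score quartile of control peaks, 59.6% and 57.6% for lists of equal length, 26.6% and 18.5% after merging within 5000 bp, and 18.2% and 9.14% outside the stretches. Guide peaks absent from the control were 32.2% and 28.1% with 50% coverage, 7.64% and 6.88% for the upper score quartile, 30.1% and 28.9% for equal lengths, and 43.4% and 41.0% outside the stretches. Control peaks absent from both guides were 66.3% with 50% coverage, 14.7% in the upper score quartile and 78.4% outside the stretches, and their excess over independence went from 1.37 to 1.16 within deciles. Regions of both guides alone numbered 53 when a control peak within 5000 bp counted as present, 99 for scores at or above each guide's median and 85 outside the stretches.

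Genes with every peak absent in both guides numbered 2335 of 4115 control-marked genes among all annotated genes. At gene ends of 2000 bp to either side they numbered 241 of 544. Genes with peaks in both guides alone numbered 39 and 9. The ratio of the latter to independence went from 12.6 to 4.86 within deciles of gene length, chosen after seeing the data. The windows at gene ends were chosen after seeing the data, because the planned windows at transcription start sites were not run, for the genes, the lists or PURPL, without strand. At the pooled median score, zinc finger coverage left was 37.3% and 8.57%, protocadherin coverage with guide 2 was 0%, fibroblast matrix coverage was 0% in both guides, and imprinted and neuronal lists had 0% with guide 2 (imprinted within its counting interval). The p53 list with guide 1 reversed, to 0% at the pooled median and 71.2% at gene ends, and the H3K9 machinery had 0% with guide 1 at gene ends. Olfactory receptors had 25.5% and 7.57% left at gene ends. Matching on length alone moved the zinc finger median change with guide 1 to percentile 0. It also moved the share left to percentile 97.4 for zinc finger genes and 0.115 for olfactory receptors with guide 2, and to 99.1 for p53 targets with guide 1. For protocadherins the share left lay at percentiles 27.1 and 23.2. Of 144 comparisons of named genes, 5 changed sign with 5000 bp flanks and 5 at the pooled median, where 58 more had 0 bp in both lists compared. At that limit the pattern held for 4 of the 10 genes covered in the control alone, 2 of the 10 in both guides alone, 4 of the 10 with the longest increases, all 10 with the largest reductions and all 5 with the longest common coverage. With flanks, USP17L30 (-2238 bp) and USP17L20 (-721 bp) with guide 2, USP17L19 (-1273 bp) with guide 1, and DUSP1 (-704 and -1236 bp) were below the control. At the pooled median, GPAM (-419 bp), PTPRN2 (-70 bp) and THBS1 (-249 bp) with guide 1 and CCN1 (-1182 bp) with guide 2 were below it, and KDM4B with guide 1 was 178 bp above it. The cause of these changes was not tested, apart from subsets that follow from the filter itself. Unknown depth limits every value.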

Other observations

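The levels for the test of the immediate-early list were set before its result was seen, but JUN was taken out of the list after a first run. The pattern that led to the test and the remaining descriptions came from the data. Several genes with short peaks in both guides are immediate-early genes, which respond within minutes to growth factors. KLF6, MCL1 and JUN were among the 24 genes with peaks in both guides and none in the control. MCL1, a survival gene of the BCL2 family, had 600 and 358 bp, and JUN, an AP-1 transcription factor gene, 270 and 136 bp, both named after their values were seen. FOS, the partner of JUN in AP-1, was covered in all 3 lists, with 913 bp in the control, 1419 bp with guide 1 and 1085 bp with guide 2. These genes are active in stimulated fibroblasts, and H3K9me3 is not usual there.

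A candidate explanation is background signal over active short genes, which would also appear in the control list. In a list of 39 other immediate-early genes, without those that led to the pattern, 2 were marked in the control (EGR1 and FOSB). This lay at percentile 85.1 of random lists matched on length. FOS, DUSP1 and CCN1, marked in the control, were not in the list, so its count depends on which genes it holds. The pattern itself, peaks in both guides and none in the control, could not occur among the 39, because genes that showed it were left out of the list. With JUN still in the list the percentile was also 85.1. With guide 1, 3 were marked (EGR1, FOSB and ID1), at percentile 98.7, and with guide 2, 0 were marked, at percentile 33.0. The control value met neither the level set for the explanation nor the level set against it, so the explanation and a change with the guides cannot be told apart with so few marked genes.

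In gene bodies, the USP17L family ran against the general direction. Of 25 members, 10 were marked in the control, 13 with guide 1 and 15 with guide 2, with 10662, 11625 and 14186 bp. With 5000 bp flanks, USP17L30 (-2238 bp) and USP17L20 (-721 bp) with guide 2 and USP17L19 (-1273 bp) with guide 1 were below the control. DUX4, in the subtelomeric repeat array of chromosome 4, had 2595, 2848 and 2778 bp. Copies of both families are close in sequence, and the copy a read came from is uncertain.

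Outside the gene-free stretches, the highest-scoring control peak without a guide peak lay in VIPR2, a neuropeptide receptor gene, at 159088935 to 159089476 on chromosome 7. Of the regions of both guides without a control peak outside the stretches, the one with the highest lower score lay at 85972649 to 85972896 on chromosome 16 (scores 79 and 130), with 0 annotated genes over it. A region in DUX4, at 190180998 to 190181224 on chromosome 4, had scores of 199 and 74.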
